A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

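Total RNA from 1 culture of the vector control strain and 1 culture of the Sj-RSH strain was measured on 2 single-colour NimbleGen arrays labelled with Cy3, per the labels. The deposited raw files hold the perfect-match intensity of each spot on a linear scale, with no background subtraction or normalisation by the authors that the file headers record. The deposited gene-level files hold RMA intensity values on a linear scale, 1 per gene and array. RMA is named in the submitters' processing notes with no version, and its background and normalisation settings are not given in the sources used here. The deposited series value table holds the same RMA intensity values under exchanged sample columns, with column medians of 8978 for the vector control and 8781 for Sj-RSH, and 1 of its entries has no value. Its scale and centring are thus those of the RMA files, and its assignment of the arrays to strains stays in conflict with the file records. A column named as a standard error in the RMA files does not scale with the gene values and was not used. The value table holds 0 columns of other samples. Raw log2 differences between the arrays correlated with RMA differences by file record at r = 0.913 across genes, so raw and RMA files of each record come from the same array.

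Because of that conflict, the arrays were treated as A (filed under the vector control) and B (filed under Sj-RSH), and all differences were computed as A minus B. The planned comparison, Sj-RSH minus vector control, follows by a change of sign under the file records and without one under the value table. The raw intensity was used as the main source and the RMA values as an alternative.

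Spot intensity was background-corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3. For bright spots this subtracted about 5633 from array A and 1680 from array B. The arrays were then quantile normalised, the 3 spots of a probe were averaged on the log2 scale, and the probes of a gene were summarised by median polish. Saturated spots, at the scanner limit of 65535, numbered 80 on array A and 8 on array B and were kept. The SD over a gene's probes (median 0.24 over genes, SE 0.054) and the SD over the 3 repeat blocks (median 0.045) describe measurement within an array and leave out all variation between cultures. The number of arrays limits the precision, and no p-value was computed. Later steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

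The raw files hold no random control probes, so the signal floor was the fallback set beforehand, the 10th percentile of gene medians of raw signal on each array, 5692 on array A and 2846 on array B. It is a fixed share of dim genes, not a measured background. Of 5868 genes, 5074 were above it on both arrays, 207 on array A alone, 207 on array B alone and 380 on neither. In the deposited RMA files the random control probes had a value of 21.4 on array A and 21.6 on array B, and 10 genes were at or below these on both arrays. On the normalised scale, the floor of an array was taken as the lowest value among genes above its raw floor. A gene above the floor on 1 array alone has a lower bound as its fold. The bound sets the gene's normalised value on the brighter array against the higher of the floor and its own value on the dimmer one. This bound equals the measured fold where its own value is the higher, and it holds only with the background correction used here. Genes were named by matching locus tags of the arrays to a RefSeq gene table of the R64 assembly, used for names alone. Of the genes, 5862 matched and 6 kept the array's name. Positions are those of the array's own annotation, whose build is not given in the sources used here.

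The groups, the floor, the 2-fold threshold, the gene lists, the rule for named genes and the alternatives were set before the data were examined, except the floor at the random control probes and the value table's assignment of the arrays, which were added afterwards. Genes were named by these rules: the 15 largest differences in each direction among genes above the floor on both arrays with at least 3 probes, 80% of them in the gene's direction; the 5 largest lower bounds in each direction; the 2 highest and 2 lowest members of each list; and a fixed set of galactose, plasmid marker, sodium pump, stress and IMP dehydrogenase genes with YBR072C-A. IMD1 is not matched by symbol on the arrays and is not analysed here, the list entry FEN1 was not matched because it is a synonym of both ELO2 and RAD27, and some other genes that these rules select are not reported here. A list's median over members above the floor on both arrays was compared with the medians of 10000 random lists of the same size matched on signal in 10 classes, and was called apart at or below percentile 2.5 or at or above 97.5. Lists share members, and genes are not replicates.

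The procedure was tested on simulated data made for the comparison of array A with array B over 5868 genes. All 50 genes shifted by log2 1.5, 50 by 2, 50 by −1.5 and 50 by −2 came out past 2-fold (100% of each), against 0 of 5668 unshifted genes. The simulated arrays differed only by these shifts and the spread over probes, with no variation between cultures, background step or normalisation. With a median SE over probes of 0.054, these results were nearly fixed in advance. They give no rate of false calls between cultures. Of 400 random lists of 30 genes, 7.25% were called apart, more than the 5% intended, and of 20 lists of 30 genes shifted by log2 0.5, 100% were. Alternatives were the RMA values and the value table, other background corrections (none, offset 0), other scalings (median, none, loess; with none, list values are relative to the median of genes above the floor on both arrays and gene values to that of all genes), other probe summaries, subsets of probes and spots, saturated spots left out, other filters on signal, a correction for position on the array, other thresholds, and for lists shared or paralogous members left out, the mean, and unmatched random lists.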

Results

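The series asked how the transcriptome of budding yeast differs when the cells make guanosine tetraphosphate (ppGpp), a nucleotide that bacteria and plastids use as an alarm signal under starvation. The host was INVSc1, a diploid laboratory strain of Saccharomyces cerevisiae. One culture carried a plasmid that expresses Sj-RSH, a plant enzyme of the RelA/SpoT family that synthesises ppGpp, from a galactose-inducible promoter. The other carried the empty vector. Both were grown for 8 h, to mid growth phase, at 30 °C in synthetic medium lacking uracil with 2% galactose. Cycloheximide, which stops translation, was added at harvest to 10 µg/ml. Total RNA of each strain was labelled with Cy3 and hybridised to 1 NimbleGen gene expression array, so there was 1 array per strain and 2 arrays in all. Each array held 351777 spots for 5868 yeast genes, and 5857 of these genes had 20 distinct probes, each spotted 3 times. The median raw spot signal was 11249 on array A and 7938 on array B.

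The arrays are called A and B because the deposited records give them to opposite strains. Array A is the one whose scanner and gene-level files are filed under the vector control, and array B the one whose files are filed under Sj-RSH. In the series value table, the vector control column equalled the gene values filed under Sj-RSH for all 5868 genes with a value, within a tolerance of 0.001, and the Sj-RSH column equalled those filed under the vector control for all 5868. No gene was equal the other way (0 of 5868). The arrays carry no probe for Sj-RSH, and 0 of their genes belong to another organism, so the transgene could not settle the assignment. Under the value table array A is the Sj-RSH strain, and under the file records array A is the vector control. Which record is right is not settled here. Every difference is therefore given as array A minus array B on the log2 scale, and its sign by strain turns with the assignment. YBR072C-A, higher on array A, is thus higher in the Sj-RSH strain under the value table's assignment and lower under the file records. With 1 array per strain no difference has a replicate check, strain and array cannot be told apart, and each SD is the spread over a gene's probes within these arrays.

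Between the arrays, 363 genes were at least 2-fold higher on array A and 213 at least 2-fold higher on array B, out of 5488 genes above the signal floor on at least 1 array. Array A thus held 63.0% of the 576 genes past that size. At 1.5-fold the majority turned, with 836 genes higher on array A and 871 on array B, or 49.0% on A. The log2 gene values of the arrays correlated with r = 0.862 across genes, which are not independent replicates, and the differences had an SD of 0.62 over genes around a median of −0.05. At least 80% of the probes pointed in the gene's direction for 575 of the 576 genes. The split also depended on the scaling: with each array scaled to the same median, 569 genes were higher on array A and 129 on array B, or 81.5% on A, and that scaling put the median gene at 0.13. In the gene values deposited by the authors 220 genes were higher on array A and 77 on array B, or 74.1% on A.

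**Figure D1:**
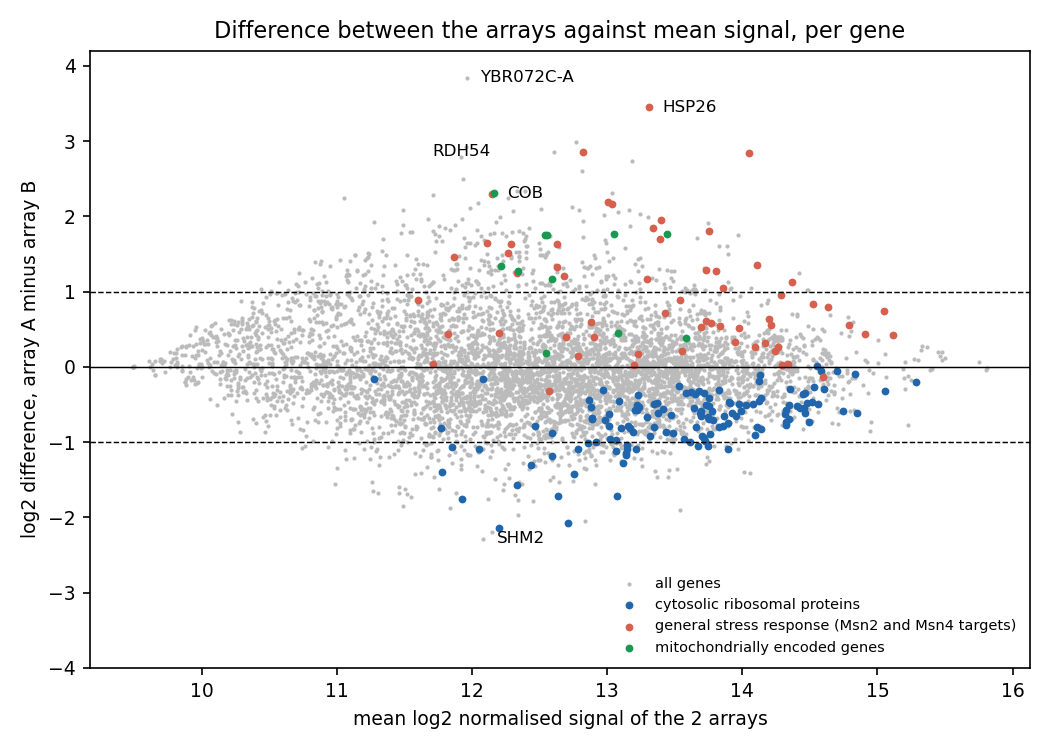
Log2 difference between array A and array B (y axis) against the mean log2 normalised signal of both arrays (x axis), 1 point per gene; dashed lines mark 2-fold. General stress genes (red) lie mostly above 0 with a median of 0.73, cytosolic ribosomal protein genes (blue) mostly below with a median of −0.65, and mitochondrially encoded genes (green) have a median of 1.34.

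Stress-response genes were among those with the largest differences towards array A. Among genes above the floor on both arrays, HSP26, a small heat shock chaperone, led with a log2 difference of 3.45 ± 0.49 (SD over 20 probes), or 10.9-fold. It was followed by YNL195C (2.99), RDH54, a DNA-dependent ATPase of recombination (2.86), GRE1, a hydrophilin (2.86), DDR2, a multi-stress response gene (2.85), RGI2 (2.73), SPG4, named for its role in stationary phase (2.61), and RRT5 (2.33). POT1, the peroxisomal thiolase of beta-oxidation (2.33), the mitochondrial cytochrome b gene COB (2.31), ADH2, the alcohol dehydrogenase that glucose represses (2.30), FMP16 (2.30), YDL218W (2.25), the stress-induced repressor XBP1 (2.19) and UIP4 (2.18) completed the leading 15. Their folds ranged from 4.54 to 10.9, and from 3.05 to 6.72 in the deposited gene values.

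Ribosomal protein genes and metabolic enzymes were among those with the largest differences towards array B. SHM2, the cytosolic serine hydroxymethyltransferase, had a log2 difference of −2.28 ± 0.36 (SD over 20 probes), or 4.87-fold. The mitochondrial carrier YHM2 (−2.19), the ribosomal scaffold protein ASC1 (−2.14), RPS22A (−2.07), the fatty acid synthase subunit FAS1 (−2.05), the cytochrome c gene CYC1 (−1.98), the flavohaemoglobin YHB1 (−1.91) and the hexokinase HXK2 (−1.79) came next. Further genes of this group were ASH1 (−1.77), RPL22B (−1.76), the ribosome assembly factor RRP5 (−1.76), RPL25 (−1.72), ARO4 of aromatic amino acid synthesis (−1.70) and the histone H2B gene HTB2 (−1.67). Their folds ranged from 3.19 to 4.87, and from 2.32 to 3.16 in the deposited gene values. Their raw signals on array A ran from 5847 for HTB2 to 11885 for YHB1, against a floor of 5692, and SHM2 was at 6101. Without background correction SHM2 was 3.00-fold and HTB2 2.23-fold higher on array B. Folds and ranks of the genes near the floor thus depend on that step, which the SD over probes does not cover.

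Some genes were above the floor on 1 array alone, so their folds are given against the floor as lower bounds, which hold only with the background correction used here. On array A these were led by YBR072C-A, a small reading frame known only by its systematic name, at least 9.85-fold higher than on array B. SPG1 of stationary phase (at least 7.15-fold), the sporulation gene SPS100 (at least 6.67-fold), SIP18, a phospholipid-binding hydrophilin (at least 5.63-fold) and AGA2, the binding subunit of a-agglutinin (at least 4.85-fold), followed. On array B they were led by the fatty acid elongase ELO2 (at least 3.66-fold), the IMP dehydrogenase IMD4 (at least 3.47-fold), RPL31A (at least 3.32-fold), the ATP synthase subunit ATP14 (at least 3.22-fold) and the B-type cyclin CLB1 (at least 3.20-fold). For SIP18, ELO2, RPL31A and ATP14 the dimmer array's own normalised value was the higher one, so the bound equals the measured fold. Without background correction all 10 measured folds were below these bounds, at 8.97, 4.18, 4.15, 3.30 and 3.00 on array A and 2.89, 2.64, 2.30, 2.35 and 2.47 on array B, in the order named. The deposited gene values gave 10.98, 4.85, 4.84, 3.74 and 3.28 on array A. On array B they gave 2.85, 3.03, 2.45, 2.44 and 2.59. Of these, only the fold of YBR072C-A was above its bound.

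YBR072C-A lies between HSP26 and RDH54. In the array's own annotation, HSP26 spans positions 382027 to 382671 of chromosome II on the forward strand, YBR072C-A spans 382855 to 383016 on the reverse strand, and RDH54 spans 383209 to 385983 on the forward strand. The genome build behind these positions is not given in the sources used here. The log2 difference was 3.45 for HSP26 and 2.86 for RDH54. YBR072C-A was at least 9.85-fold higher on array A, or 8.97-fold without background correction and 10.98-fold in the deposited gene values. The flanking genes YBR071W (−0.62 ± 0.19, SD over 20 probes) and PFF1 (−0.33 ± 0.19, SD over 20 probes) lay on the other side of 0. Raw signals of YBR072C-A were 20411 on array A and 1272 on array B.

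**Figure D2:**
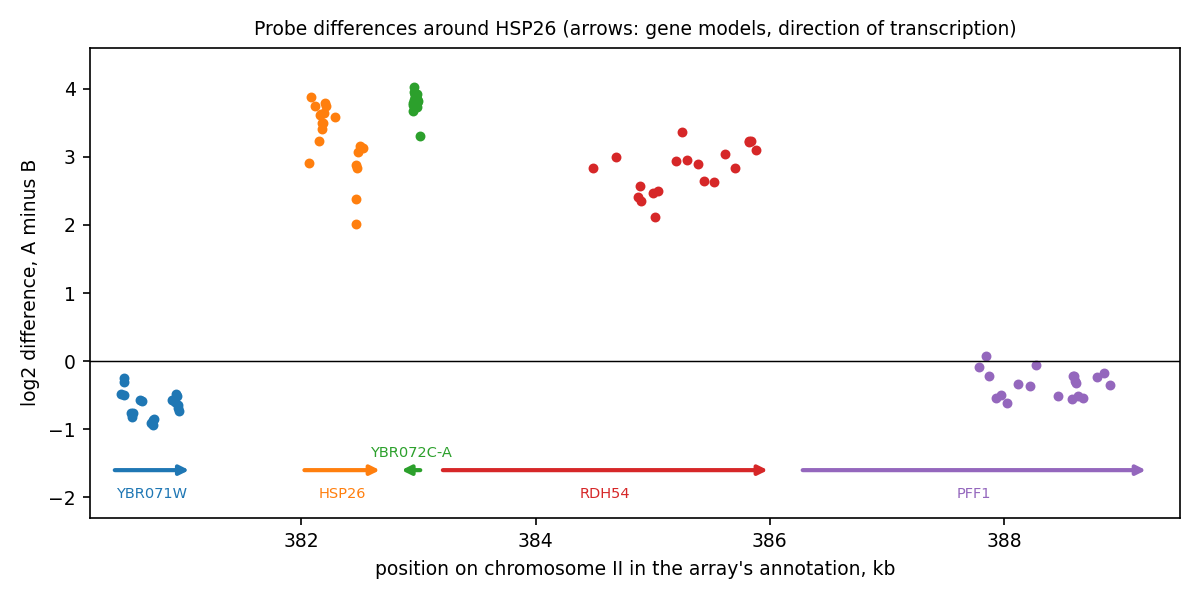
Log2 difference of each probe, array A minus array B (y axis), against position on chromosome II in kb (x axis) for HSP26, YBR072C-A, RDH54 and their flanking genes; arrows are gene models in the direction of transcription. All probes of the 3 central genes lie above 0, with gene values of 3.45 for HSP26 and 2.86 for RDH54, against −0.62 for YBR071W and −0.33 for PFF1. YBR072C-A is below the floor on array B, so no gene value is given for it.

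Stress genes were higher on array A as groups. The list of cytosolic heat shock proteins and chaperones, which also holds some mitochondrial chaperones, had a median difference of 0.87 over 33 members above the floor on both arrays. Of these, 15 were at least 2-fold higher on array A, 0 on array B, and 18 were within 2-fold. Besides HSP26, the membrane heat shock protein HSP30 stood at 1.91, whereas HCH1, a regulator of Hsp90, was at −0.76 and the mitochondrial chaperonin HSP10 at −0.07. The general stress list, genes known as targets of the transcription factors Msn2 and Msn4, had a median of 0.73 over 60 members, with 24 at least 2-fold higher on array A and 0 on array B. GRE1 led it after HSP26, the catalase CTT1 was at 1.27 and HSP12 at 0.84, while MSN4 itself was at −0.32 and the secretory glycoprotein gene YGP1 at −0.14. Both medians were above those of all 10000 random lists of the same size matched on signal.

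Trehalose and glycogen genes were also higher on array A, with a median of 0.52 over 21 members and 4 past 2-fold, led by GIP2, a regulator of glycogen-related phosphatase (1.52), and the vacuolar trehalase ATH1 (1.32). PGM1 (−0.59) and the glycogen synthase GSY2 (0.02) were at the low end. Autophagy genes had a median of 0.65 over 33 members, with 5 at least 2-fold higher on array A and 28 within 2-fold. ATG8, the ubiquitin-like protein of the autophagosome membrane, stood at 2.09 ± 0.17 (SD over 20 probes) and ATG34 at 1.29, against −0.69 for ATG27 and −0.16 for ATG13. The osmotic stress and glycerol list had a median of 0.31 over 24 members, at percentile 99.9 of the random lists, with 5 past 2-fold. GRE1 and PAI3 (1.64) led it, and the glycerol-3-phosphate dehydrogenase GPD2 (−0.58) and the regulator SKO1 (−0.42) were lowest. Without the members it shares with other lists, this median was −0.059 over 10 genes and the call was lost.

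Not every stress list stood apart. Oxidative stress defence had a median of 0.06 over 31 members, within the range of the random lists (percentile 89.2), with GRE2 at 1.64, the peroxisomal catalase CTA1 at 1.53, the thioredoxin TRX1 at −0.77 and GRX4 at −0.68. The median passed the upper limit with the first repeat spot of each probe alone (0.15), with genes above the median of mean signal (0.31) and with a mean in place of the median (0.21). The unfolded protein response list was within the random range at −0.12 over 19 members, with ERO1 at 0.55, SIL1 at 0.31, INO1 at −0.95 and SEC63 at −0.62. Proteasome subunits were within it at −0.11 over 34 members, with 0 past 2-fold in either direction, the regulator RPN4 at 0.84, RPN1 at 0.59, RPN9 at −0.77 and PRE3 at −0.64. Multidrug resistance genes were within it at −0.13 over 24 members, and the polyamine transporter TPO3 (−1.47) was their 1 gene past 2-fold, while PDR16 was at −0.86, FLR1 at 0.55 and PDR15 at 0.45.

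The protein synthesis machinery was lower on array A than on array B. Cytosolic ribosomal protein genes had a median of −0.65 over 131 members, of which 130 were below 0 and 1 above. Of these, 24 were at least 2-fold higher on array B, 0 on array A, and 107 were within 2-fold. ASC1 and RPS22A were lowest, and RPS6A (0.01) and RPS6B (−0.05, or 0.18 with median scaling) highest. Ribosome biogenesis factors had a median of −0.68 over 112 members, with 23 at least 2-fold higher on array B and 0 on array A; RRP5 and UTP4 (−1.63) were lowest, and RPF1 (0.89) and RRP36 (0.28) highest. Translation initiation and elongation factors had a median of −0.48 over 35 members, from −1.002 for PRT1 and −0.88 for TIF35, both of initiation factor eIF3, to 0.10 for TEF2 and 0.40 for HYP2. All 3 medians were below those of all 10000 random lists. The list of RNA polymerase I and III subunits also holds transcription factors of RNA polymerase I, such as RRN7. It had a median of −0.46 over 20 members (percentile 0.34), with RPA34 at −1.51, RPA190 at −1.23, RRN7 at 0.46 and RPA14 at 0.72. That call was lost with median scaling (−0.25), without normalisation between arrays (−0.32 relative to the median of genes above the floor on both arrays) and among genes above the median of mean signal (−0.41).

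**Figure D3:**
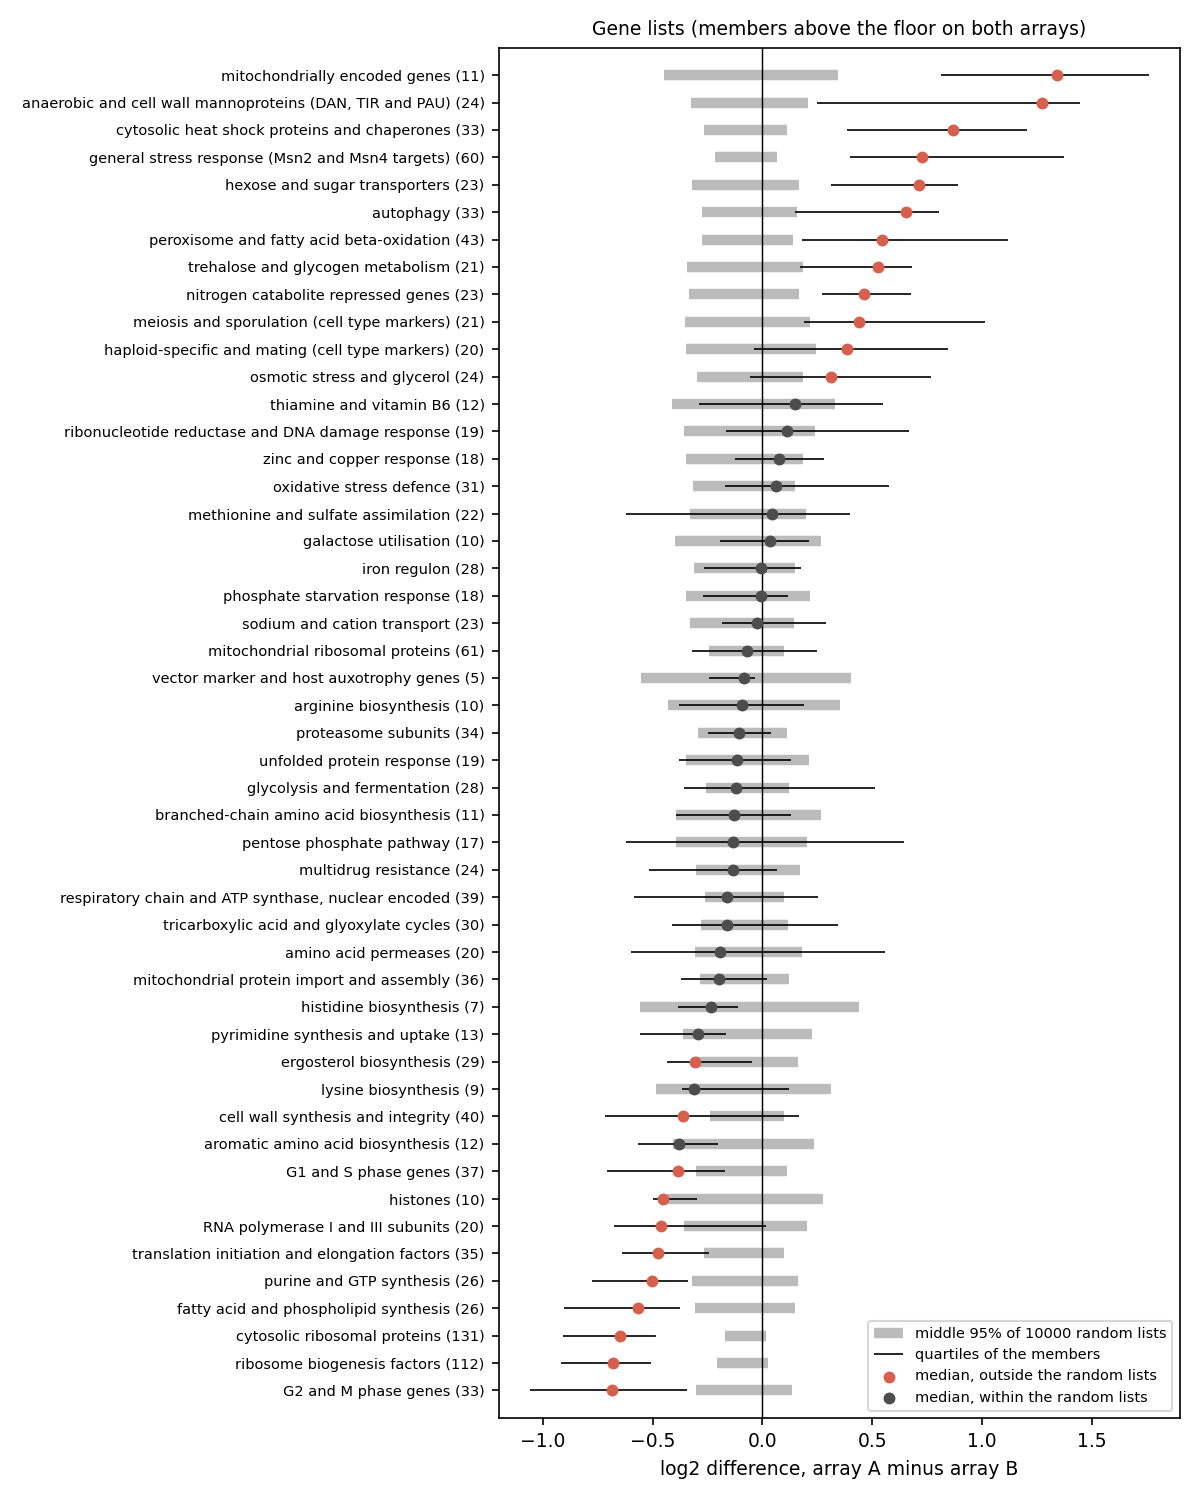
Median log2 difference, array A minus array B (x axis), of the 49 gene lists with the number of members above the floor on both arrays in brackets; thin lines span the quartiles of the members and grey bars the middle 95% of 10000 random lists matched on signal. Red points mark the 23 medians outside the grey bars, 12 on the side of array A and 11 on the side of array B, from 1.34 for mitochondrially encoded genes to −0.68 for G2 and M phase genes.

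Of the 49 gene lists fixed before the data were examined, 23 lay outside the middle 95% of the random lists, 12 towards array A and 11 towards array B, where 2.45 would do so by chance if lists were independent. In a test of the procedure, 7.25% of 400 random lists of 30 genes were called outside, more than the 5% intended. These percentiles describe these 2 arrays and carry no error between cultures. Markers of other cell types were among the lists outside, as meiosis genes had a median of 0.44 and haploid-specific genes one of 0.39, both towards array A like the stress lists.

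Mitochondrially encoded genes had a median of 1.34 over the 11 of 19 members above the floor on both arrays, with 8 at least 2-fold higher on array A and 0 on array B. COB (2.31 ± 0.65, SD over 20 probes) and COX3 (1.77 ± 0.25, SD over 20 probes) were highest, and COX1 (0.18 ± 0.83, SD over 20 probes) and OLI1 (0.39 ± 0.14, SD over 20 probes) lowest. Over all 19 members, the dim ones included, the median was 0.75, below the 0.96 of the DAN, TIR and PAU list over all its members. This lower median depends on the background correction, which compresses dim genes. Each member below the floor on both arrays had a larger difference in the deposited gene values. BI2 was at 0.48 here and 1.78 there, and Q0255 at 0.54 and 1.86. The intron frames AI1, AI2, AI3 and AI4 overlap the COX1 gene model, so these members are not separate observations. The lists of nuclear genes for mitochondria did not stand apart. The nuclear-encoded respiratory chain and ATP synthase list was within the random range at −0.16 over 39 members, with the NADH dehydrogenase NDE2 at 1.93, STF1 at 1.11, ATP5 at −1.03 and CYC1 at −1.98. The mitochondrial ribosomal protein list was chosen by gene name alone, so the function of each member was not checked. It lay within the random range at −0.07 over 61 members, with MRP8 at 1.29, MRX14 at 0.92, MRP51 at −0.83 and NAM9 at −0.73. Mitochondrial import and assembly genes were within it at −0.20 over 36 members, with PAM17 at 0.69, MDM10 at 0.53, TOM71 at −0.92 and OXA1 at −0.91.

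Of the lists on carbon metabolism, those of peroxisomes and of sugar transporters stood apart. Peroxisome and beta-oxidation genes had a median of 0.54 over 43 members, with 15 at least 2-fold higher on array A and 0 on array B, led by POT1 and the acyl-CoA oxidase POX1 (2.11), against −0.77 for PEX6. Hexose and sugar transporters had a median of 0.71 over 23 members, with HXT5 at 1.98, HXT10 at 1.74, the galactose permease GAL2 at 0.16 and the glucose sensor RGT2 at −0.19. Many HXT genes are similar copies, and signal shared between their probes was not checked, so the members do not count as separate observations. Both medians were above those of all 10000 random lists. Glycolysis and fermentation genes were within the random range at −0.12 over 28 members, with ADH2 and the dehydrogenase TDH1 (1.14) at one end and HXK2 and the triose phosphate isomerase TPI1 (−1.07) at the other. The tricarboxylic acid and glyoxylate list was within it at −0.16 over 30 members, although 3 members were at least 2-fold higher on array A, led by the isocitrate dehydrogenase IDP3 (1.78) and the acetyl-CoA synthetase ACS1 (1.71). LSC1 was at −0.83. The medians and means of these lists had opposite signs, the means being 0.03 for glycolysis and 0.08 for the tricarboxylic acid list. The pentose phosphate list was within the random range at −0.13 over 17 members with a mean of 0.15, and its paralogs lay far apart, TKL2 at 2.13 and TKL1 at −1.14. SOL4 was at 2.17 and RKI1 at −1.03.

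The lists tied to the galactose medium, the plasmid and salt transport did not stand apart. The galactose utilisation list was within the random range at 0.04 over 10 members with a mean of −0.04, and 0 were past 2-fold. GAL1 was at −0.25 ± 0.13, GAL7 at 0.09 ± 0.19 and GAL10 at −0.02 ± 0.12 (SD over 20 probes each), while the regulators GAL3, GAL80 and GAL4 were at −0.75, −0.42 and 0.27. The vector marker and host auxotrophy list, which holds URA3, HIS3, LEU2, TRP1 and GAL1, was within it at −0.08 over 5 members. URA3, the marker of the plasmid, was at −0.04 ± 0.37 (SD over 20 probes), HIS3 at −0.08, LEU2 at 0.20 and TRP1 at −0.47. With median scaling GAL1, GAL10 and URA3 turned positive, at 0.01, 0.21 and 0.14. Sodium and cation transport genes were within it at −0.02 over 23 members. Among these, the sodium pump genes ENA1, ENA2 and ENA5, which are close copies of each other, were at 0.44, 0.36 and −0.50. PMA2 (1.18) and HAL1 (0.68) were highest, and TRK1 was at −0.45.

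Purine and GTP synthesis genes were lower on array A. Their list had a median of −0.51 over 26 members (percentile 0.03), with 5 at least 2-fold higher on array B and 0 on array A, and SHM2 and the adenine phosphoribosyltransferase APT1 (−1.56) were lowest. IMP dehydrogenase, the first enzyme of the GTP branch, is encoded by paralogs that differed in sign, with IMD2 at 0.88 ± 0.18 and IMD3 at −1.03 ± 0.53 (SD over 20 probes each). IMD4, above the floor on array B alone, was at least 3.47-fold lower on array A, or 2.64-fold without background correction. FCY22 was at 0.52. Pyrimidine genes were within the random range at −0.29 over 13 members, with URA8 at 0.00, URA6 at −0.93 and URA7 at −0.86, but passed the limit with odd-numbered probes (−0.38) and with the mean (−0.37). The ribonucleotide reductase and DNA damage list was within it at 0.11 over 19 members. Its reductase subunits differed, RNR3 at 1.45 and RNR1 at −1.25, and DDI3 was at 0.92 and SML1 at −1.01.

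Genes repressed by good nitrogen sources were higher on array A, with a median of 0.46 over 23 members, above that of all 10000 random lists, and 3 past 2-fold. These were the proline oxidase PUT1 (2.08), the succinate semialdehyde dehydrogenase UGA2 (2.06) and the GABA permease UGA4 (1.31), and DAL7 (−0.47) and MEP3 (−0.28) were lowest. None of the amino acid synthesis lists lay outside the random range. Their medians were −0.09 for arginine (10 members, from −0.66 for ORT1 to 0.72 for ARG56), −0.23 for histidine (7 members, from −0.82 for HIS1 to −0.06 for HIS5), −0.31 for lysine (9 members, from −0.87 for LYS14 to 0.17 for LYS5) and −0.13 for branched-chain amino acids (11 members, from −1.04 for LEU9 to 0.34 for ILV2). The aromatic list, at −0.38 over 12 members, from ARO4 and ARO1 (−1.24) to ARO3 (0.02), passed the limit under some alternatives, among them the mean (−0.51). Methionine and sulfate genes were at 0.04 over 22 members with a mean of −0.05, the S-adenosylmethionine synthetase SAM2 being at −1.56, MET6 at −1.12, SUL2 at 0.93 and MET16 at 1.05. Amino acid permeases were at −0.20 over 20 members, with TAT1 at −1.22, MUP1 at −0.89 and MMP1 at 0.85, and passed the limit among genes above the median of mean signal (−0.48).

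Lipid synthesis genes were lower on array A. Fatty acid and phospholipid synthesis had a median of −0.57 over 26 members, below that of all 10000 random lists, with 25 of 26 below 0 and 3 past 2-fold. FAS1 and the phospholipid methyltransferase CHO2 (−1.53) were lowest, the desaturase OLE1 was at −0.15 and GPT2 at 0.91. Ergosterol genes had a median of −0.31 over 29 members (percentile 2.27), with HMG1 at −0.75, MVD1 at −0.74, UPC2 at 0.64 and HES1 at 1.17. Their call was lost in the deposited gene values (−0.24), with a mean in place of the median (−0.20), with other probe summaries (both −0.31) and with the last repeat spot alone (−0.30).

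At the cell surface the mannoprotein genes of the DAN, TIR and PAU families, known from anaerobic growth, had a median of 1.27 over 24 members, with 16 at least 2-fold higher on array A and 0 on array B. PAU9 (1.59) and PAU13 (1.498) were highest, and the oxygen-responsive genes HEM13 (−0.38) and ROX1 (−0.14), also in this list, were lowest. PAU genes are near-identical copies, so their probes may share signal and the members do not count as separate observations. Other cell wall genes had a median of −0.36 over 40 members (percentile 0.06), with 5 at least 2-fold higher on array B, led by the glucanase family genes SCW11 (−1.46) and SCW4 (−1.36), and 1 on array A, PIR3 (1.27). FLO10 was at 0.94.

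Cell cycle genes were lower on array A. G2 and M phase genes had a median of −0.68 over 33 members, below that of all 10000 random lists, with 10 at least 2-fold higher on array B and 0 on array A; ASH1 and the mitotic cyclin CLB2 (−1.49) were lowest and NDD1 (0.17) and HST4 (0.09) highest. G1 and S phase genes had a median of −0.38 over 37 members (percentile 0.37), from the G1 cyclin CLN3 (−1.30) and RNR1 (−1.25) to GIC1 (0.27) and the replication protein RFA3, which stood apart at 1.80. The 10 histone genes had a median of −0.45 (percentile 2.03). Their copies differed, with HTB2 at −1.67 and HHT1 at −1.38 but HHT2 at −0.19 and HTA1 at 0.06, and the call was lost with odd-numbered probes (−0.42), with the first (−0.43) or last (−0.42) repeat spot alone and among genes above the median of mean signal (−0.45).

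Markers of other cell types were higher on array A. Meiosis and sporulation genes had a median of 0.44 over the 21 of 51 members above the floor on both arrays (percentile 99.98), with 6 at least 2-fold higher on array A, led by the sporulation glucoamylase SGA1 (1.72) and MUM3 (1.16), while SPO12 (−0.69) and RED1 (−0.14) were lowest. Haploid-specific and mating genes had a median of 0.39 over 20 of 37 members (percentile 99.7), with 4 past 2-fold. The a-factor genes MFA1 and MFA2 led them at 1.96 ± 0.12 and 1.92 ± 0.09 (SD over 20 probes each), and KSS1 (−0.90) and PRM5 (−0.39) were lowest. The haploid list lost its call among genes above the median of mean signal, where 7 members had a median of 0.16. Lists on metal, phosphate and vitamins were within the random range. Phosphate genes were at −0.01 over 18 members, with PHO89 at 1.29, CTF19 at 1.08, VTC2 at −0.60 and PHO90 at −0.49. The iron regulon was at −0.01 over 28 members, with CCC2 at 0.83, TIS11 at 0.59, FET3 at −0.87 and BIO2 at −0.80. Zinc and copper genes were at 0.08 over 18 members, with CTR2 at 0.79, CUP1-2 at 0.70, ZRT2 at −0.79 and ZRT1 at −0.31. Thiamine and vitamin B6 genes were at 0.15 over 12 members, with PET18 at 1.77, SNO2 at 1.14, THI80 at −0.63 and PDC2 at −0.54, and passed the limit without a filter on signal (0.49 over 22 members).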

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

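The floor at the random control probes and the value table's assignment of the arrays were chosen only after the data were seen; the other alternatives were planned. No paired analysis was possible because each strain has 1 culture and 1 array. An alternative based on present or absent calls was not run, since the files analysed hold none. Signal over background limits the dim genes most, because normexp compresses them towards 0 and the floor is a fixed share of genes.

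The count of genes at least 2-fold higher on array A, 363, became 220 in the deposited RMA values and in the value table, 168 without background correction, 569 with median scaling, 132 among genes above the median of mean signal, 836 at 1.5-fold and 98 at 3-fold. The count for array B, 213, became 77, 77, 57, 129, 101, 871 and 26 in that order. With no background correction the differences shrank to a slope of 0.723 of those reported, and in the RMA values to 0.776. By strain, 363 genes were higher and 213 lower in the Sj-RSH sample under the value table's assignment, against 213 and 363 under the file records. YBR072C-A, Sj-RSH minus vector control, turned from −3.84 to 3.84 under that assignment and to 3.46 in the value table as labelled; its signal on array B is below the floor, so its fold is given as at least 9.85 with the background correction used here, against 8.97 without one.

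Of 1122 list medians under 23 alternatives, 1095 kept their side of the limits, 14 were no longer outside them, 12 newly were, and 1 of a list outside them turned its sign. Some medians of lists within the limits also changed sign. Of the 23 lists outside the random range, 18 were so under every alternative run. The 23 alternatives are not separate checks, since some repeat others. For lists, the filter on both arrays is the reported analysis itself, and the value table repeats the RMA values. No normalisation gives the same percentiles as median scaling. Part of the 1095 was thus fixed in advance. The osmotic list turned to −0.059 over the 10 members left when shared ones were left out. The RNA polymerase list went to −0.25 with median scaling, −0.32 without normalisation (relative to the median of genes above the floor on both arrays) and −0.41 among brighter genes. The ergosterol list, reported at −0.31 and percentile 2.27, went to −0.24 in the RMA values and the value table, −0.30 with the last spot and −0.20 with the mean. With the mean over probes or the median of probe differences it stayed at −0.31, and only its percentile crossed the limit. The median of probe differences leaves gene differences unchanged, so there only the random lists matched on signal changed. The histones went to −0.42 with odd probes, −0.43 with the first spot, −0.42 with the last spot and −0.45 among brighter genes, and the haploid list to 0.16 among brighter genes. Lists that newly passed were oxidative stress (0.15 with the first spot, 0.31 among brighter genes, 0.21 with the mean), aromatic amino acids (−0.42 with odd probes, −0.44 with no filter and with the random control floor, −0.51 with the mean), permeases (−0.48 among brighter genes), pyrimidines (−0.38 with odd probes, −0.37 with the mean) and thiamine (0.49 with no filter and with the random control floor). Apart from the ergosterol call with the median of probe differences, the cause of these changes was not tested.

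For the 223 named genes, 3086 of 3345 values stayed within 1 SD over probes of the reported one and 259 moved further, 78 of them without background correction and 64 in the RMA values, and 0 genes past 2-fold changed sign. The median of probe differences repeats the reported values of these genes, and the value table repeats the RMA values. Part of the 3086 was thus fixed in advance. Near 0, median scaling also turned RPS6B, HSP10, YGP1, ATG13, HIS5, OLE1 and ROX1 positive, to 0.18, 0.36, 0.07, 0.15, 0.05, 0.16 and 0.14.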

Other observations

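The tests of the exchanged arrays, of background and normalisation and of growth stage were chosen only after the result was seen; the tests of read-through, strands, array position, non-specific signal and chromosomes were set before. Genes singled out in the next paragraph were chosen after their values were seen.

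The haploid-specific list held genes known from a-type cells that were higher on array A. Besides MFA1 (1.96), MFA2 (1.92) and AGA2 (above the floor on array A alone), the a-specific gene ASG7 was at 1.67, and the receptor for alpha-factor, STE2, at 0.77. BAR1, the a-cell protease that degrades alpha-factor, was above the floor on array A alone. STE6, the exporter of a-factor, was below the floor on both arrays. Of the genes known to be specific to alpha cells, SAG1 was at 0.18 and MF(ALPHA)2 at −0.06, and STE3 and MF(ALPHA)1 were below the floor on both arrays. Of single genes known from both haploid types, GPA1 was at 0.87, NEJ1 at 0.84, AXL1 at 0.47 and the pheromone-induced gene FUS1 at 1.24, and FUS3 was above the floor on array A alone. Over the whole list, 14 of 20 members above the floor on both arrays were higher on array A and 6 on array B, and among genes above the median of mean signal the list's median was 0.16 over 7 members, within the random range. The cause of this was not tested.

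Genes and reading frames of the mitochondrial genome did not move as a block. Probes were not assigned to introns or exons. In COX1, whose gene model spans positions 13818 to 26701 of the mitochondrial chromosome, the intron-encoded reading frames AI1, AI2 and AI3 were at 1.34, 1.17 and 1.28, AI4 was at 0.45, AI5_ALPHA was above the floor on array B alone, and COX1 itself was at 0.18 with an SD of 0.83 over its 20 probes. These frames overlap the COX1 model, so their probes do not measure separate genes. COX2 (1.76), COX3 (1.77), ATP6 (1.76) and the endonuclease gene SCEI (1.76) were nearly equal, and OLI1 was at 0.39. VAR1 and ATP8 were below the floor on both arrays.

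The value table and the file records give the arrays to opposite strains. An exchange in 1 of the records is a candidate explanation. All 5868 genes were equal crosswise, as such an exchange would give. This equality is also what revealed the conflict, so it is no separate test. Which record was exchanged stays open: 0 features on the arrays come from outside yeast, so no probe reads the transgene, and the alternatives cannot be told apart from the probes. An effect of Sj-RSH with either sign therefore stays open for every gene.

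HSP26, YBR072C-A and RDH54 lie side by side and were all higher on array A. If HSP26 transcripts ran on into RDH54 and faded with distance, its probes would lose the difference. Instead the difference rose along RDH54, with Spearman's rho 0.612 (bootstrap 95% interval 0.225 to 0.833, over 20 probes). The mean was 2.64 over the 5 nearest probes and 3.12 over the 5 farthest. No fall was thus seen within the probed part of RDH54. Probes of 1 gene can differ by more than this rise, as those of HSP26 ran from 2.01 to 3.88. The bootstrap also treats neighbouring probes as independent. A trend with distance therefore cannot be told apart from differences in probe response. Nor can these probes decide on read-through of even level, which predicts no fall. The probes also start at position 1282 of the gene, so a fall nearer HSP26 is out of view. Arrays that do not tell strands apart could give YBR072C-A signal from either side. Overlapping opposite-strand genes correlated in their differences at r = 0.348 over 12 pairs against 0.128 over 2230 adjacent pairs, a gap of 0.220 with an interval from −0.342 to 0.594, so this cannot be told apart from strand-specific signal with so few pairs. A shared response of the locus to the strain difference, with or without ppGpp, remains untested.

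General stress genes were higher and ribosomal protein genes lower on array A, a gap of 1.38 between the list medians. The lowest gap over the settings run, 1.08, came without background correction, against 1.16 in the RMA values and 1.36 with loess. This argues against background correction and normalisation as its sole cause. Most other settings vary neither step, and a shift of a whole array, as in median scaling, cancels in the gap. Signal trends over the array are also argued against, since correction for position left 1.38. More non-specific signal on array A would raise dim genes. The stress median was still 0.62 over the 50 of 60 members above the median of mean signal. That mean includes array A, so genes raised there pass more easily. The filter also kept most members, so this cannot decide on non-specific signal. The pattern is also known from slower growth and from cultures nearer the end of their sugar, and a difference in growth stage between the cultures could give it. With 1 culture per strain, growth stage and strain cannot be told apart, and an effect of ppGpp stays among the open explanations, as untested.

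A whole chromosome gained or lost in 1 strain could shift its genes together. The largest distance of a nuclear chromosome's median from that of all genes was 0.0874, on chromosome VI, far below the shift that 1 extra copy would give a diploid, which argues against this. Neighbouring genes did share part of their differences: r was 0.164 over 1109 divergent pairs, 0.0945 over 1121 convergent pairs and 0.108 over 2078 pairs on the same strand, against −0.006 over 5000 random pairs.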
